A study of Mus musculus with 12 samples.

How the data were processed

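Messenger RNA from the dorsal root ganglia of lumbar levels 3 to 5 was sequenced in 12 libraries from C57BL/6 mice aged 8 weeks after birth, per the labels: females and males, each after sciatic nerve injury or a sham operation, with 3 libraries in each of the 4 groups. The time between the operation and the dissection and the kind of injury are not given in the sources used here. Per the labels' protocols, libraries were made from polyadenylated RNA with the QuantSeq 3′ mRNA kit, which reads the 3′ ends of transcripts, and were sequenced as single reads on a NextSeq 500. The deposited files hold raw counts per gene symbol, 1 file per library, per the file headers. The submitters' processing notes name the genome build mm10 and the tools Bowtie2 and bedtools, with no version or role. How strand, multiply mapped reads, duplicate molecules and genes that share sequence were treated is not given in the sources used here, so genes whose exons overlap are marked as uncertain. Each file held 23282 rows and 23238 distinct symbols; 35 symbols stood on more than 1 row, and the 44 extra rows were summed with the row of the same symbol. The values were whole numbers with totals that differed between libraries.

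The total count was 12476606 to 15520746 per library, so that 3 counts in a single library correspond to 0.191 to 0.244 CPM. The floor used where a group had no count was 3 counts over all libraries of the group together, which is lower in CPM. Reads carry no stated molecular identifiers, so floors cover counting error only. The ribosomal RNA row Rn45s was kept in the totals, and a fit without it was run as an alternative. Within groups the Pearson correlation of log2 CPM was 0.910 to 0.974, and the chi-square per gene of any pair of replicates was at least 8.62, far above sampling noise, so no pair looked like 1 library deposited in duplicate. Positions came from the RefSeq annotation of GRCm38.p6, the build also called mm10: of 15036 tested genes 14333 were placed by symbol, 660 by a synonym and 43 not at all. Exon overlaps, transcript length and GC content came from GENCODE release vM21.

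Groups were taken from the labels. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and its group argument, libraries were scaled by TMM factors (0.914 to 1.07), and 1 negative binomial model with a coefficient per group was fitted to all 12 libraries with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), so that all groups share the estimate of the spread. The common biological coefficient of variation was 0.275. Quasi-likelihood F tests, two-sided, were made for 6 contrasts: injury averaged over the sexes, injury in females, injury in males, the sex by injury interaction (the change in males minus that in females), and males minus females in sham and after injury. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes with an adjusted p below 0.05 were called. Group levels are CPM on TMM-scaled totals, as mean ± SD of 3 libraries, and log2 changes are given with the standard error of the model. The agreement of the sexes was given as a correlation across genes and as the overlap of calls. The log2 changes of females and males come from different libraries, but their calls share the estimate of the spread over all 12.

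Lists of genes, 40 in all, were written before the data were examined, as were the design, the rule for named genes and most of the alternatives. They cover regeneration transcription factors, regeneration growth and cytoskeleton genes, sensory neuropeptides, nociceptor markers, mechanoreceptor and proprioceptor markers, voltage-gated sodium channels, potassium channels, analgesic receptors, pan-neuronal genes, satellite glia markers, glial and tissue reactivity, myelinating Schwann cell genes, repair Schwann cell genes, macrophage markers, MHC class II, T and NK cell markers, B cell markers, neutrophil markers, cytokines and chemokines, complement, interferon-stimulated genes, cell cycle, endothelial markers, mural cell markers, fibroblast and matrix genes, adipocyte markers, skeletal muscle markers, erythroid markers, central nervous system markers, cholesterol synthesis, fatty acid synthesis, PPAR alpha targets, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, ER stress and amino acid response, immediate early genes, sex hormone receptors, Y-linked genes and X-linked genes expressed from the inactive X. Some lists share members, such as Scn10a and Scn11a of the nociceptor and sodium channel lists and C4b of the complement and reactivity lists. Lists with at least 3 tested members, 37 of them, were tested against the other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the lists; camera with a correlation estimated per list and fry were alternatives.

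The rule for named genes had 5 parts. For injury averaged over the sexes it took the 10 called genes with the largest increase and the 10 with the largest decrease among genes with a mean CPM of 5 or more whose 3 SNI and 3 sham values did not overlap in either sex, in the direction of the change. For each comparison of the sexes it took all called genes if there were 10 or fewer, and otherwise the 5 with the largest increase and the 5 with the largest decrease. For the interaction it took up to 10 called genes by adjusted p, or the 5 with the smallest unadjusted p where none was called. For each list it took up to 4 called members with the largest change in injury averaged over the sexes and the most abundant tested member. It also took Atf3 and the members of the sex-linked lists as label checks. Some genes that the rule took are not reported here, and they were left out of the results for named genes but kept in the fits and the list tests. By chance, 3 values against 3 lie fully apart in a given direction in 5% of cases within a sex.

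The alternatives were DESeq2 1.42.0 with its Wald test, RLE and upper-quartile factors, no filter or a filter of 5 CPM in 3 libraries, the replicate number as a block, each library left out in turn, a log2 change of 1 added to the threshold, a robust estimate of the spread, fits of only the 6 libraries compared, and tests without the sex-linked lists. Leaving out both libraries that stood apart, limma's voom with sample quality weights and leaving out the row Rn45s were added after the data were seen. The steps were tested on simulated counts drawn from the real means and library sizes with 200 changed genes per comparison. Of 100 genes changed 2-fold and 100 changed 4-fold, 59% and 85% were recovered for injury averaged over the sexes, 40% and 81% for injury in females, 29% and 72% for injury in males, 8% and 51% for the interaction, 40% and 76% for sex in sham, and 39% and 79% for sex after injury, with 4 to 11 false calls. Figures were drawn with matplotlib 3.10.9.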

Results

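Messenger RNA was measured in the dorsal root ganglia of C57BL/6 mice aged 8 weeks after birth, the ganglia that hold the cell bodies of the sensory neurons whose axons run in the sciatic nerve. Ganglia from lumbar levels 3 to 5 came from males and females after sciatic nerve injury (SNI) or a sham operation, which gave 4 groups of 3 libraries and 12 libraries in total. The libraries were made with a kit that reads the 3′ ends of polyadenylated transcripts. The total count per library lay between 12476606 and 15520746, and between 15961 and 16834 genes had at least 1 count. The labels do not say that the 3 replicates of a group were separate animals, so the p-values measure the spread between these libraries, which may be technical. A precursor of ribosomal RNA, Rn45s, took 6.14% to 11.2% of the counts, with the lowest share in Male sham replicate 3.

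Sex and injury labels were compared with transcripts that mark them. Xist, the RNA that silences an X chromosome in female cells, was at 133 to 171 CPM (counts scaled by the library totals) in the 6 female libraries and at no more than 0.154 CPM in the 6 male libraries. The summed CPM of the Y-linked genes was at least 80.7 in every male library and at most 0.524 in every female library. Atf3, a transcription factor induced in sensory neurons by axon damage, was at 275 CPM or more in every SNI library and at 56.7 CPM or less in every sham library. None of the 12 libraries went against its label.

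Separation of the libraries by injury was seen on the second principal component of log2 CPM, which held 16.4% of the variance. The first component held 27.2% and set apart Male SNI replicate 2, with a score of 99.9, and Female sham replicate 2, with a score of 47.5. The remaining libraries scored between -32.8 and 0.963 on it.

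**Figure D1:**
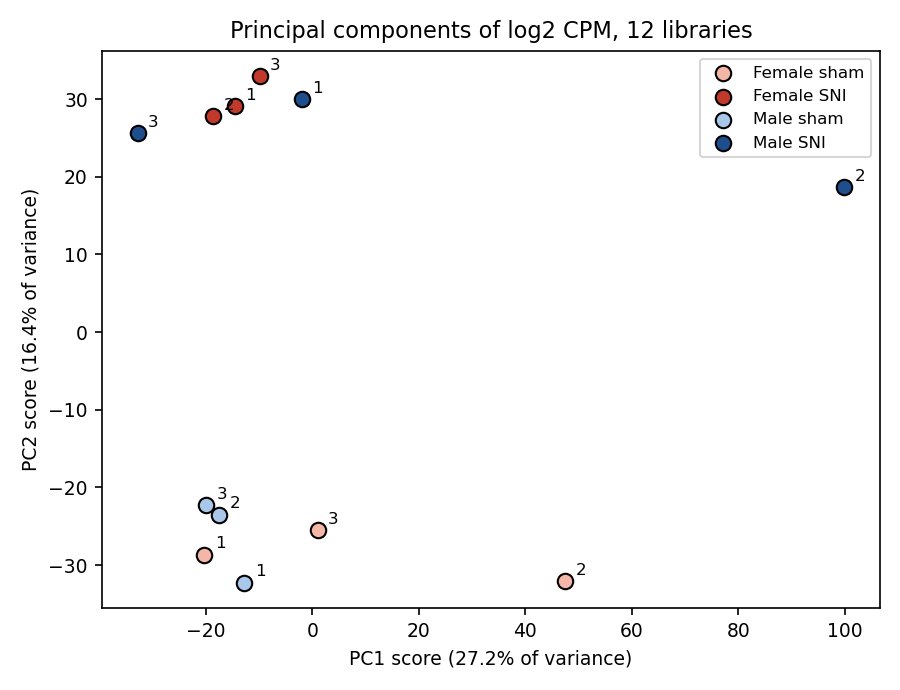
Scores of the 12 libraries on the first 2 principal components of log2 CPM, colored by sex and treatment, with replicate numbers beside the points. The 6 SNI libraries lie above 0 and the 6 sham libraries below 0 on the second component, and Male SNI replicate 2 and Female sham replicate 2 lie to the right on the first.

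The first question was what sciatic nerve injury changed in the ganglia of both sexes. Averaged over males and females, the neuropeptide gene Npy rose the most of the genes with a mean of 5 CPM or more whose SNI and sham libraries did not overlap in either sex, by 3.79 ± 0.17 on the log2 scale (SE; adjusted p = 7.91e-09), from 17.8 ± 4.67 to 227 ± 17.5 CPM in females (SD, n = 3) and from 17.8 ± 2.54 to 267 ± 83.8 CPM in males. Atf3 (chromosome 1, 191170296 to 191183333, GRCm38) rose by 2.63 ± 0.09 (adjusted p = 7.2e-10), from 48.4 ± 4.16 to 335 ± 22.2 CPM in females and from 53.4 ± 2.84 to 297 ± 27.5 CPM in males. Sprr1a, a gene linked to axon outgrowth, rose by 2.79 ± 0.12 (chromosome 3, 92483954 to 92485881; adjusted p = 4.93e-09). Within the same limits on CPM and overlap, the other genes with large increases were Cckbr, a receptor for cholecystokinin and gastrin, at 3.09 ± 0.22, Wfdc3 at 2.87 ± 0.24, the carbonic anhydrase gene Car3 at 2.60 ± 0.22, the neuropeptide genes Nts at 2.44 ± 0.13 and Gal at 2.27 ± 0.09, Tmem88b at 2.37 ± 0.20 and the tubulin gene Tubb6 at 2.27 ± 0.13. Decreases were smaller in size. Thrsp, a regulator of lipid synthesis genes, fell by 1.30 on the log2 scale with an SE of 0.13 (chromosome 7, 97412933 to 97417550; adjusted p = 3.26e-05), from 28.4 ± 5.24 to 10.4 ± 0.269 CPM in females and from 33.3 ± 2.27 to 14.9 ± 2.29 CPM in males. Changes of the other genes at this end were -1.22 for Chodl, -1.18 for LOC100862268, for which no position was found, -1.18 for Nog, a secreted BMP antagonist, -1.14 for D130009I18Rik, -1.13 for Kndc1, -1.10 for the itch receptor gene Mrgpra3, -1.07 for Whrn and -1.06 for Gm4980, with adjusted p between 0.000132 and 0.00918. Rab37 was at -1.10 (adjusted p = 0.0209) and no longer passed without Female SNI replicate 1 or 3, Female sham replicate 3 or Male sham replicate 1 or 3, where its change was -0.98, -1.10, -1.09, -1.04 and -1.09.

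Of 15036 genes tested with edgeR's quasi-likelihood test, 980 passed a Benjamini-Hochberg adjusted p of 0.05, and 569 of them rose and 411 fell. A change of at least 2-fold was estimated for 251 of the genes that rose and 23 of those that fell. Without Male SNI replicate 2 the count was 1766, without both it and Female sham replicate 2 it was 1848, and with sample quality weights in limma it was 2274. Without Male sham replicate 1 the count was 631, and without Female SNI replicate 1, 2 or 3 it was 648, 652 and 626.

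**Figure D2:**
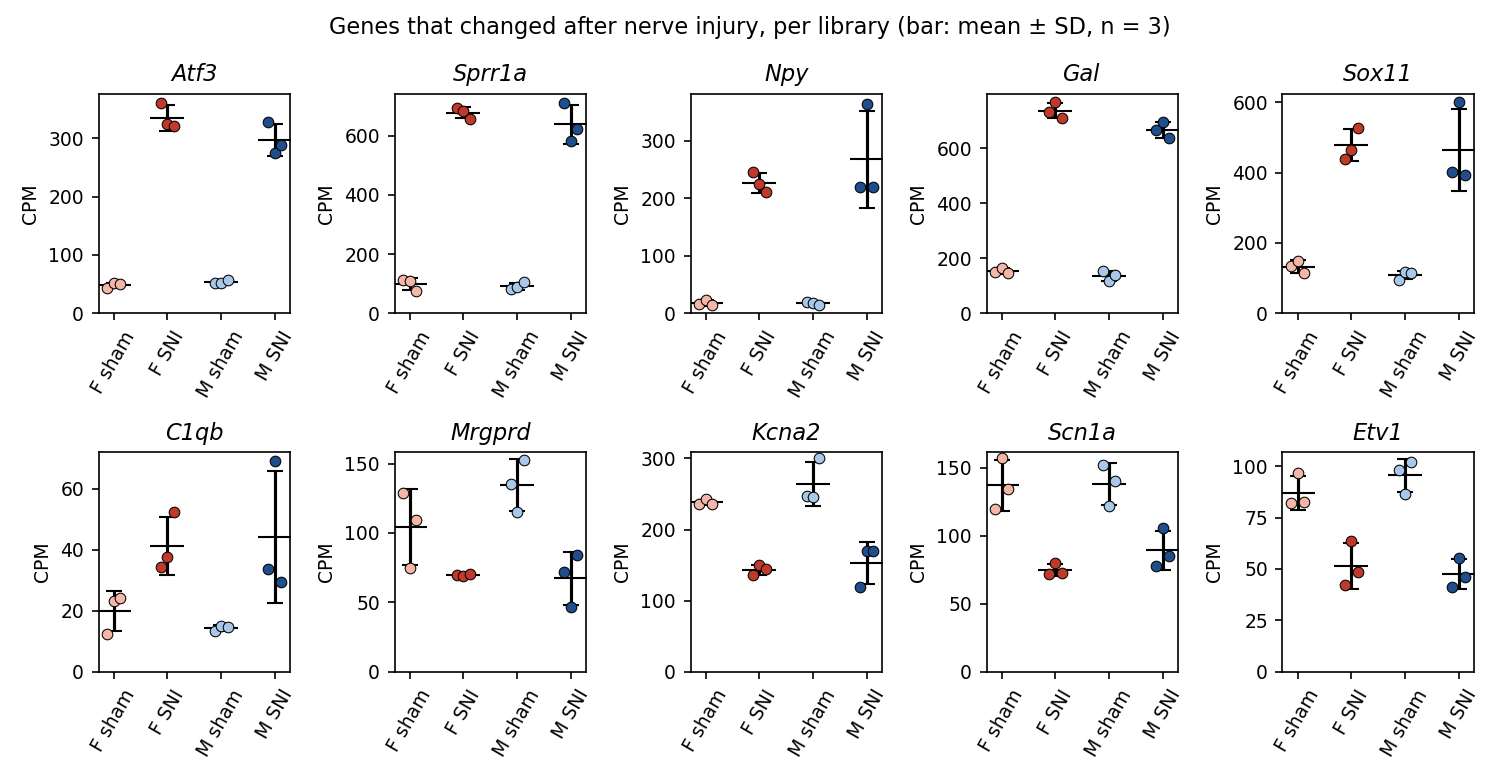
CPM of 10 named genes in each library, with 1 point per library and bars at the mean ± SD of the 3 libraries of a group (F, female; M, male). In the panels of Atf3, Sprr1a, Npy, Gal, Sox11 and C1qb the SNI libraries lie above the sham libraries of the same sex, and in those of Mrgprd, Kcna2, Scn1a and Etv1 they lie below.

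Genes known for their part in axon regeneration rose after injury in both fixed lists. In the list of growth and cytoskeleton genes, 22 of 29 tested members rose and none fell, with a median log2 change of 1.28. Besides Sprr1a and Tubb6 they included the orphan receptor gene Gpr151 at 3.01 ± 0.55 and Tuba1a, the most abundant member, at 0.49 ± 0.10 (3668 ± 33.9 to 5666 ± 544 CPM in females and 4092 ± 104 to 5234 ± 1057 CPM in males). Among the regeneration transcription factors, 9 of 16 rose and none fell, with a median of 0.96. Sox11 rose by 1.97 ± 0.12 (chromosome 12, 27334268 to 27342718; 133 ± 18.2 to 478 ± 45.5 CPM in females and 109 ± 11.5 to 465 ± 117 CPM in males), Nfil3 by 1.79 ± 0.21 and Klf6 by 1.08 ± 0.08. Stat3, the most abundant of these factors, was at 0.29 ± 0.08. With 1 library left out it passed only without Male SNI replicate 1 or 2, and its exons overlap those of Stat5a, so its value is uncertain. Adjusted over the list alone, 23 growth genes and 13 transcription factors rose. The camera test of each list against the other genes gave adjusted p = 8.28e-86 for the growth genes and 7.3e-34 for the transcription factors, and adjusted p = 1.12e-05 and 0.00119 with an estimated correlation.

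Neuropeptide genes went in both directions. Of 13 tested, 5 rose and 2 fell, and 7 and 3 did so when adjusted over the list alone. Npy, Nts and Gal rose as given above, and Crh, the gene of corticotropin-releasing hormone, rose by 1.80 ± 0.15. The 2 that fell, named after their values were seen, were Tac1 at -0.44 ± 0.10 and Calcb at -0.40 ± 0.09, genes of the substance P and CGRP families of nociceptors. Calca, the most abundant member, was at 1188 ± 144 and 1127 ± 146 CPM in female sham and SNI libraries and at 1363 ± 106 and 967 ± 312 CPM in the males (adjusted p = 0.313). The list as a whole was shifted up (median 0.64; adjusted p = 4.64e-21, and adjusted p = 0.00042 with an estimated correlation).

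Lists of sensory neuron subtype markers and of ion channel genes were shifted down after injury, with 4 to 9 members of each called. Of 16 nociceptor markers 6 fell and none rose, with a median of -0.44 (adjusted p = 6.7e-08). Mrgprd, a receptor of nonpeptidergic nociceptors, fell by 0.79 with an SE of 0.15, from 104 ± 27.3 to 69.7 ± 0.926 CPM in females and from 134 ± 18.6 to 67.3 ± 19.1 CPM in males, and Otoa fell by 0.89 on the same scale. Of 12 mechanoreceptor and proprioceptor markers 6 fell and none rose, with a median of -0.48 (adjusted p = 1.98e-08), among them Etv1 at -0.88 ± 0.12, Cntnap2 at -0.57 ± 0.07 and the neurofilament gene Nefh, the most abundant, at -0.50 ± 0.11. Of 21 potassium channel genes 9 fell and none rose, with a median of -0.40 (adjusted p = 3.18e-10), led by Kcns1 at -0.84 ± 0.13 and Kcna2 at -0.76 ± 0.10. These calls held with an estimated correlation, with adjusted p = 0.00816, 0.00229 and 0.0423. Of 11 voltage-gated sodium channel genes 4 fell, including Scn1a at -0.75 ± 0.10 and Scn8a at -0.49 ± 0.07, and none rose (median -0.32; adjusted p = 6.72e-05, but adjusted p = 0.107 with an estimated correlation). The other 2, Scn10a at -0.46 ± 0.12 and Scn11a at -0.38 ± 0.10, also count among the nociceptor markers that fell. With 1 library left out, Scn10a passed only without Male SNI replicate 2. Scn11a passed only without Female SNI replicate 2, Female sham replicate 1 or Male SNI replicate 2. Male SNI replicate 2 lacked the shift of both channel lists: relative to their mean over the libraries, the medians of potassium and sodium channel genes were 0.07 and 0.20 in it, -0.33 to -0.16 and -0.34 to -0.14 in the other SNI libraries, and 0.12 to 0.39 and 0.12 to 0.28 in the sham libraries. Adjusted over the list alone, 11 nociceptor, 8 mechanoreceptor and proprioceptor, 13 potassium channel and 5 sodium channel genes fell, and 1 nociceptor marker rose.

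The lists of macrophage, complement and reactivity genes were shifted up. Of 19 macrophage markers 15 rose and none fell, with a median of 1.14 (adjusted p = 8.37e-24). The protease gene Ctss rose by 1.31 ± 0.16 (21.9 to 32.4 CPM in female sham and 45.3 to 64.6 CPM in female SNI libraries, and 13.7 to 23.4 and 45.0 to 58.1 CPM in the males), the complement component C1qb by 1.34 ± 0.23 and the phagocytic receptor gene Trem2 by 2.26 ± 0.45. Csf1r, whose exons overlap those of Hmgxb3 and whose value is therefore uncertain, was the most abundant member at 1.28 ± 0.17. Of 11 complement genes 5 rose, led by C3 at 1.52 ± 0.21 and Cfp at 1.21 ± 0.20 (median 0.82; adjusted p = 5.84e-07), and of 10 glial and tissue reactivity genes 3 rose, led by Timp1 at 1.48 ± 0.22 (median 0.48; adjusted p = 6.72e-05). With an estimated correlation these 3 lists had adjusted p = 0.00243, 0.00336 and 0.039. When adjusted over the list alone, 18 macrophage, 8 complement and 5 reactivity genes rose, and none of these lists held a gene that fell. Among the called genes, C1ra (complement, 0.84 ± 0.23) and Lcn2 (reactivity, 1.31 ± 0.33) passed in few fits that left out 1 library. C1ra did so without Female sham replicate 1, Male SNI replicate 1 or 3 or Male sham replicate 3. Lcn2 did so without Female SNI replicate 1, Male SNI replicate 2 or Male sham replicate 3.

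For 5 further lists that were shifted up the call was lost with an estimated correlation. Of 8 neutrophil markers 2 rose, of which Ltf was at 1.21 ± 0.28 (list median 0.96; adjusted p of the list = 0.000547, and adjusted p = 0.361 with an estimated correlation). Ltf no longer passed without Female SNI replicate 3, Male SNI replicate 1 or Male sham replicate 1, where its change was 1.11, 1.08 and 1.11. S100a8, the other, was at 1.02 ± 0.25. Its call ended without Female SNI replicate 2 or 3 and without Female sham replicate 1 or 2. It also ended without Male SNI replicate 1 and without Male sham replicate 1 or 2. Of 8 cytokine and chemokine genes 2 rose, of which Ccl7 was at 2.05 ± 0.46, and at 1.96 and not called without Female SNI replicate 2 (list median 1.37; adjusted p = 0.00132, and adjusted p = 0.107 with an estimated correlation). Interleukin gene Il6, the other, passed at adjusted p = 0.0498 with no count in the male sham libraries and no more than 1.84 CPM in any library, and it passed only in the fits that left out Female sham replicate 1, Male SNI replicate 1 or Male SNI replicate 2. Of 20 ribosomal protein genes 1 rose, Rplp0 at 0.40 ± 0.10, which passed only in the fits that left out Female sham replicate 2 or Male SNI replicate 1, 2 or 3 (list median 0.19; adjusted p = 0.00908, and adjusted p = 0.107 with an estimated correlation). Of 4 adipocyte markers 1 rose, Car3, which other tissues also express (list median 0.17; adjusted p = 0.004, and adjusted p = 0.23 with an estimated correlation). Of 11 ER stress and amino acid response genes 1 rose, Chac1 at 1.25 ± 0.23 (list median 0.29; adjusted p = 0.0352, and adjusted p = 0.107 with an estimated correlation). That last call ended without Female sham replicate 2 or 3, without Male SNI replicate 2 and without Male sham replicate 3 (adjusted p = 0.0532, 0.0608, 0.0686 and 0.0554). When adjusted over the list alone, 4 neutrophil, 3 cytokine, 1 ribosomal protein, 1 adipocyte and 1 ER stress gene rose.

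Single libraries carried the calls of 2 lists for injury averaged over the sexes. None of 8 skeletal muscle markers passed over all genes, all 8 passed upward when adjusted over the list alone, and the list passed at adjusted p = 0.00933 (median 2.63; adjusted p = 0.512 with an estimated correlation). Acta1, the most abundant of them, was at 445 CPM in Male SNI replicate 1 and at 1.95 to 15.4 CPM in the other libraries, and without Male SNI replicate 1 the list had adjusted p = 0.179. None of 12 interferon-stimulated genes passed over all genes, 4 rose when adjusted over the list alone, and the list passed at adjusted p = 0.00195 (median 0.92; adjusted p = 0.512 with an estimated correlation). Rsad2 was at 100 CPM in Male SNI replicate 2 and at 16.6 to 35.8 CPM in the other libraries, and without Male SNI replicate 2 the list had adjusted p = 0.112. The interferon list also passed camera for injury in females. That call ended without Female SNI replicate 2 or 3 or Female sham replicate 1 or 2 (adjusted p = 0.119, 0.103, 0.105 and 0.0916).

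Downward shifts of 2 more lists rested on few genes. Of 11 analgesic receptor genes only Oprl1, the nociceptin receptor gene, fell, at -0.90 ± 0.21 (list median -0.34; adjusted p = 0.0234, and adjusted p = 0.107 with an estimated correlation). That list had adjusted p = 0.0503 without Female sham replicate 1, and the call of Oprl1 itself ended without Female SNI replicate 1 or 3, Female sham replicate 1 or Male sham replicate 3, where its log2 change was -0.84, -0.87, -0.81 and -0.77. Among 6 tested sex hormone receptor genes Prlr fell, at -0.91 ± 0.23 (list median -0.32; adjusted p = 0.0299, and adjusted p = 0.232 with an estimated correlation). Prlr passed in the fits without Female SNI replicate 3, Female sham replicate 2, Male SNI replicate 2 or 3 or Male sham replicate 1, and not in the other 7, where its change lay between -0.91 and -0.79. The list no longer passed without any 1 of 11 libraries, with adjusted p from 0.0539 to 0.247, and it passed only where Male sham replicate 1 was left out. Adjusted over the list alone, 1 analgesic receptor gene fell.

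The other 18 lists tested did not pass for injury averaged over the sexes. Of 10 satellite glia markers 1 rose, Glul at 0.55 ± 0.07 (adjusted p of the list = 0.371). Exons of Glul overlap those of Teddm2 over 67 bases, so its value is marked as uncertain, although Teddm2 had a mean of only 0.407 CPM. Of 12 pan-neuronal genes Elavl3 rose by 0.32 ± 0.08, and Rbfox3 and Nefm fell by 0.35 and by 0.46, the last with exons that overlap Nefl and an uncertain value. Elavl3 passed only in the fits that left out Female sham replicate 1, Male SNI replicate 1, 2 or 3 or Male sham replicate 3, and lay between 0.30 and 0.34 in the other 7. Rbfox3 passed only without Female SNI replicate 1, Female sham replicate 1 or Male SNI replicate 2 or 3, and lay between -0.36 and -0.30 in the other 8. Nefm passed only without Female sham replicate 1 or Male SNI replicate 2, and lay between -0.48 and -0.36 in the other 10. The list did not pass (median -0.12; adjusted p = 0.12), and this list passed downward without Female sham replicate 1 (adjusted p = 0.0481) and without Male SNI replicate 2 (adjusted p = 0.0183). Of 10 fatty acid synthesis genes 1 rose, Fads1 at 0.38 ± 0.08, a call that ended without Female SNI replicate 3, where it was at 0.34 (adjusted p of the list = 0.515). No member was called in the lists of myelinating Schwann cell genes (adjusted p = 0.349), repair Schwann cell genes (0.449), MHC class II (0.169), B cell markers (0.764), cell cycle (0.517), endothelial markers (0.277), mural cell markers (0.449), fibroblast and matrix genes (0.494), erythroid markers (0.349), cholesterol synthesis (0.313), PPAR alpha targets (0.651), oxidative phosphorylation (0.349), immediate early genes (0.349), Y-linked genes (0.775) and X-linked genes expressed from the inactive X (0.635). The MHC class II list passed upward without Male sham replicate 2 (adjusted p = 1.89e-05), the library in which H2-Aa was at 117 CPM against 20.7 to 60.7 CPM elsewhere, and the erythroid list passed downward without Female SNI replicate 3 (adjusted p = 0.0149). Adjusted over the list alone, 1 satellite glia, 1 repair Schwann cell, 1 mural cell, 1 B cell, 1 pan-neuronal and 2 fatty acid synthesis genes rose, and 5 pan-neuronal genes and 1 B cell gene fell. With 2 of 10 and 2 of 8 members tested, the lists of T and NK cell markers and of central nervous system markers were too small to test, and no mitochondrially encoded gene was present under the names of its list. In these 2 small lists the most abundant genes, Lck and Aqp4, had adjusted p = 0.559 and 0.552.

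**Figure D3:**
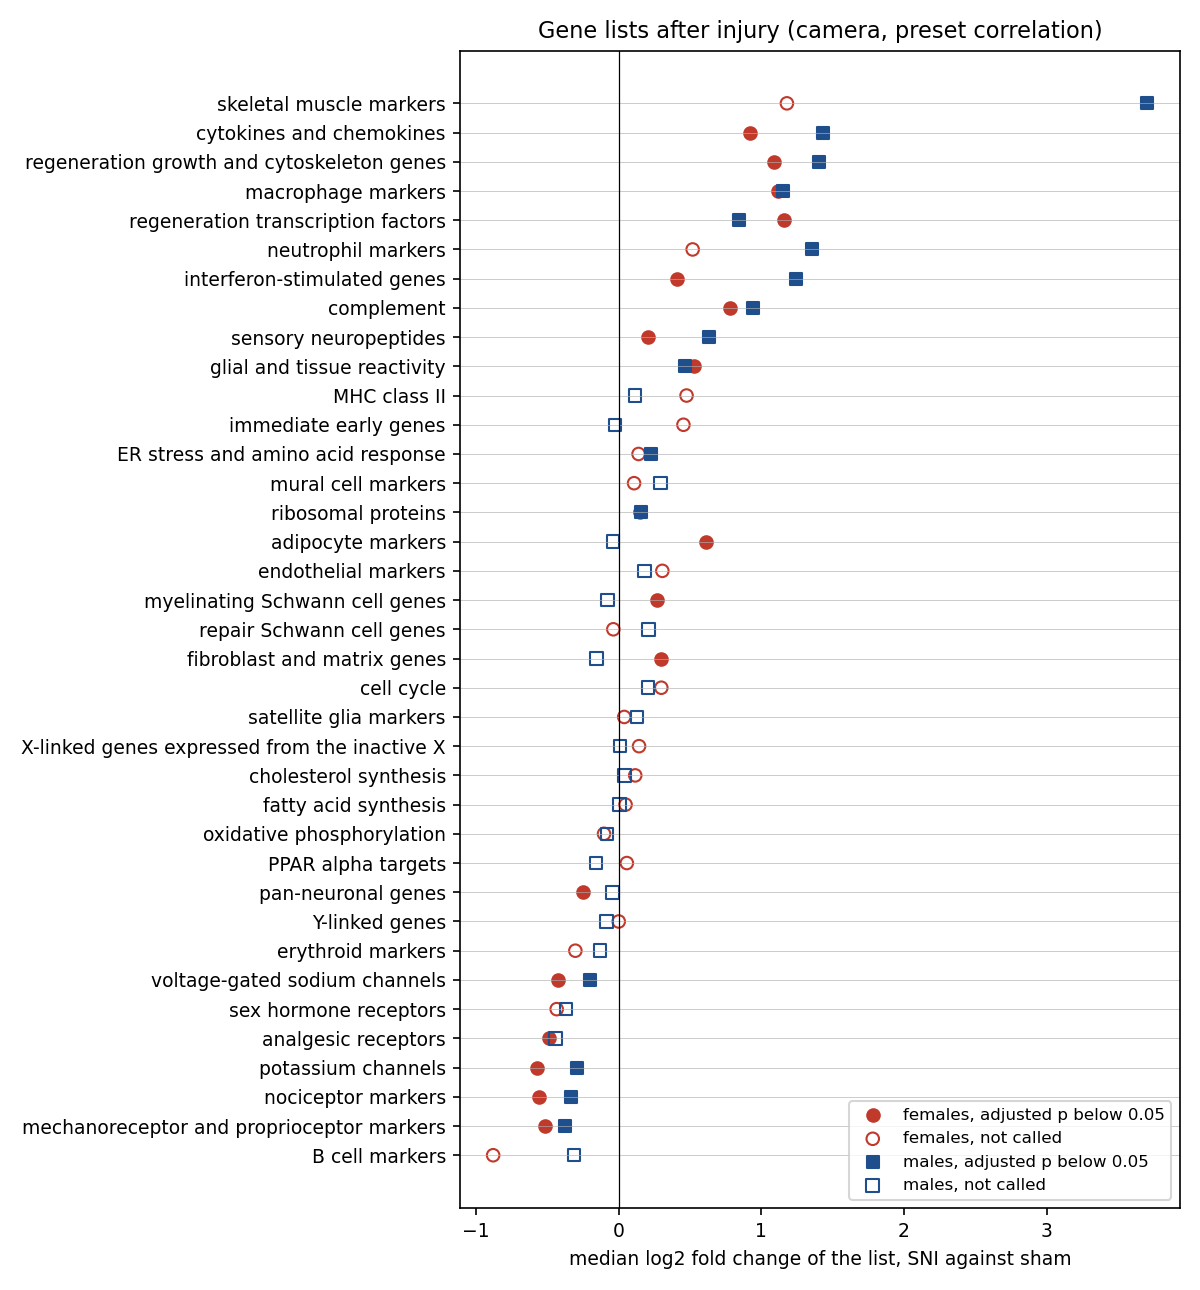
Median log2 change after injury of the tested members of each of 37 gene lists, in females (circles) and males (squares). Filled symbols mark lists with a camera adjusted p below 0.05 at the preset correlation; the macrophage and regeneration lists lie to the right of 0 and the neuron subtype and channel lists to the left in both sexes.

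The second question was how each sex responded. In females 435 genes passed edgeR's test, of which 241 rose and 194 fell, and in males 321 passed, of which 248 rose and 73 fell. Atf3, Sprr1a, Npy, Gal and Sox11 rose in both, with Atf3 at 2.79 in females and 2.47 in males and Sox11 at 1.85 and 2.09. Upward calls shared by both sexes numbered 137, against 3.97 for independent lists of these lengths, and shared downward calls numbered 38, against 0.942. No gene rose in one sex and fell in the other, and none of the genes called in either sex passed the interaction test. Of 104 genes called upward in females alone 102 had a positive change in males, and of 156 called downward in females alone 147 had a negative change in males. The corresponding counts for males alone were 107 of 111 upward and 34 of 35 downward.

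Across all 15036 genes the changes in the sexes had a Pearson correlation of 0.319 and a Spearman correlation of 0.184, and 54.1% had the same sign. Across the 980 genes called on average these were 0.831 and 0.873, and 979 genes had the same sign, although those genes were picked for a change in the average of both sexes. Genes are not independent replicates, so no p is given. The macrophage markers passed in each sex, with a median change of 1.12 and 8 members rising in females and 1.15 and 8 in males, as did the regeneration growth genes (1.09, 19 of 29 and 1.40, 16 of 29) and transcription factors (1.16, 6 of 16 and 0.85, 6 of 16). Called lists numbered 17 in females and 16 in males, of which 8 and 8 were called with an estimated correlation.

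These counts changed when a single library was left out. Leaving out a library of the sex tested also leaves fewer libraries there, which can lower the count, so such falls do not single out any library. The number of called genes in females was 155, 169 and 178 without Female SNI replicate 1, 2 or 3, 240, 217 and 175 without Female sham replicate 1, 2 or 3, and 1176 without Male SNI replicate 2. In males it was 186, 467 and 601 without Male SNI replicate 1, 2 or 3, and 137, 165 and 141 without Male sham replicate 1, 2 or 3. The correlation across all genes was lowest without Male SNI replicate 3, at 0.172.

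**Figure D4:**
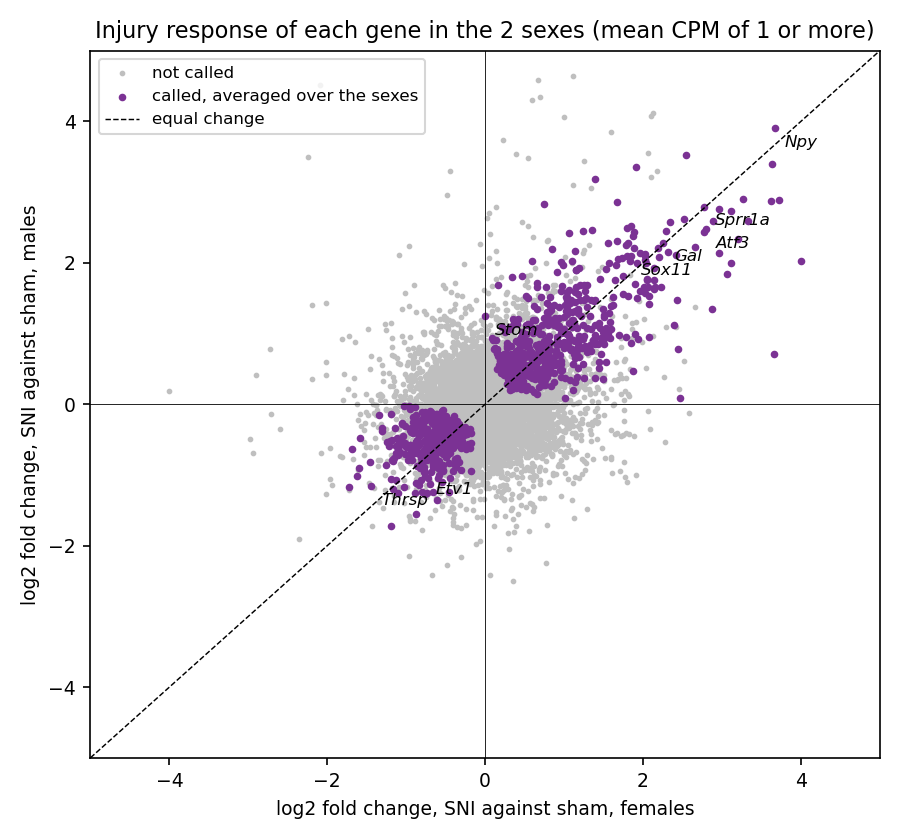
Log2 change after injury of each gene with a mean CPM of 1 or more, in females (horizontal axis) and males (vertical axis), with genes called on average in purple; 5 of 13785 genes fall outside the axes. Nearly all called genes lie in the quadrants of equal sign, and Stom, named for its interaction, lies near 0 in females.

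The third question was whether the response differed between the sexes, the comparison named by the title of the study. No gene passed the sex by injury interaction in edgeR's test, and none passed with DESeq2 or with limma's voom weights either. At an unadjusted p under 0.05 there were 1100 genes in edgeR, against 752 that chance gives, and the smallest adjusted p was 0.647. This excess varied with the libraries in the fit, each of which had fewer libraries when 1 was left out. The count was 675 without Female sham replicate 2, 736 without Female SNI replicate 2 and 748 without Male sham replicate 3, all under that of chance. Without any other single library it stayed above that of chance, from 788 without Female SNI replicate 1 to 2839 without Male SNI replicate 3. The 5 genes with the smallest unadjusted p, none of which passed, were Rbm4, Stom, Gm14164, Nudt22 and Slc35c2. Stom, a membrane protein gene, was at 71.0 ± 6.04 and 71.0 ± 17.0 CPM in female sham and SNI libraries and at 34.8 ± 6.80 and 82.8 ± 9.31 CPM in the males, a difference in log2 change of 1.25 (unadjusted p = 0.000332). Nudt22 was at 22.5 ± 0.544 and 8.82 ± 1.01 CPM in females and 14.5 ± 2.11 and 13.0 ± 2.12 CPM in males, a difference of 1.20. For Slc35c2 the difference was 1.06. Rbm4, with a difference of -1.32 (unadjusted p = 0.00029), and Gm14164, with one of 1.79, have exons that overlap Gm21992 and Nrsn2, so their values are uncertain. For Atf3 the difference between the sexes was -0.32 (unadjusted p = 0.0728, adjusted p = 0.647), for Npy 0.24, for Sprr1a 0.02, for Gal 0.03 and for Sox11 0.25.

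None of the 37 lists passed for the interaction, and 9 had an unadjusted camera p under 0.05, where the smallest adjusted p was 0.0861, for the myelinating Schwann cell and the fibroblast lists. With an estimated correlation and with fry none passed. Lists passed in every fit that left out 1 library except those without Female sham replicate 1 and without Male SNI replicate 3. The most, 5, passed without Male SNI replicate 2, where neutrophil markers had adjusted p = 7.99e-08 with a higher change in males. In simulated counts with changes planted in the interaction, 8% of 2-fold and 51% of 4-fold differences were recovered, so differences near 2-fold were mostly not detectable at this size.

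The last comparison was between the sexes within each treatment. In sham libraries 6 genes passed, and the same 6 passed after injury: the Y-linked Ddx3y, Uty, Eif2s3y and Kdm5d were higher in males, and Xist and Tsix were higher in females. Uty (chromosome Y, 1085187 to 1245773) was at 15.2 to 21.0 CPM in male sham and 8.61 to 14.6 CPM in male SNI libraries and had no count in any female library, which made it at least 244-fold higher in sham males and at least 174-fold higher in SNI males, taking 3 counts over the female group as the floor. On the same floor Eif2s3y was at least 141-fold and 143-fold higher, and Kdm5d at least 52.3-fold higher in sham males. Ddx3y was at 60.1 to 94.4 CPM in males and up to 0.524 CPM in females. Xist was at 152 ± 16.3 CPM in female sham libraries and Tsix at 102 ± 7.15 CPM, and the exons of these genes overlap on opposite strands, so their counts cannot be told apart where strand was not used. Of the X-linked genes that escape silencing none but Xist passed over all genes. Kdm5c was at 47.4 ± 4.65 CPM in female and 32.0 ± 2.10 CPM in male sham libraries, a log2 difference of -0.57 (adjusted p = 0.938), and Eif2s3x at 46.2 ± 4.15 and 24.6 ± 3.18 CPM after injury, a difference of -0.91 (adjusted p = 0.425).

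Lists of Y-linked and X-linked genes passed in both treatments and with an estimated correlation, with adjusted p = 5.27e-06 and 0.000137 in sham and 6.47e-06 and 2.4e-05 after injury. Adjusted over the list alone, all 4 tested Y-linked genes were higher in males in both treatments, and 4 and 5 of 8 X-linked genes were lower. In sham libraries 6 other lists passed at the preset correlation. Myelinating Schwann cell genes (adjusted p = 0.0071), immediate early genes and B cell markers (0.0359 each) were shifted toward males, and complement genes (0.0359), glial and tissue reactivity genes (0.0385) and macrophage markers (0.039) toward females. None passed with an estimated correlation, at adjusted p = 0.683, 0.683, 0.22, 0.22, 0.437 and 0.683 in the order given. Schwann cell genes also lost the call without Female sham replicate 1 or 2 (adjusted p = 0.143 and 0.0988), complement genes without Female sham replicate 1 or 3 or Male sham replicate 1 (0.0709, 0.109 and 0.148), and immediate early genes without Female sham replicate 2 or 3 or Male sham replicate 2 (0.0988, 0.0793 and 0.169). Macrophage markers lost it without Female sham replicate 2 or 3, Male sham replicate 1 or 3 or Male SNI replicate 2 (0.0988, 0.18, 0.142, 0.221 and 0.0642), and reactivity genes without Female sham replicate 1 or 2, Male sham replicate 2 or Male SNI replicate 2 or 3 (0.12, 0.0634, 0.225, 0.0642 and 0.0547). B cell markers lost it without Female sham replicate 1, 2 or 3, Male sham replicate 1 or Male SNI replicate 2 or 3 (0.143, 0.0988, 0.0793, 0.0716, 0.128 and 0.0547). The B cell list held only 3 tested genes, with means of 0.596 to 0.739 CPM over all libraries, so it rested on few counts.

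After injury 7 lists other than the sex-linked ones passed. Skeletal muscle markers (adjusted p = 1.3e-05), sodium channel, potassium channel and erythroid genes (0.025 each) and neutrophil markers (0.044) were higher in males, and complement genes and fibroblast and matrix genes (0.0359 each) were lower. With an estimated correlation these lists had adjusted p = 0.678, except complement at 0.282. Skeletal muscle markers lost the call without Male SNI replicate 1 (0.244), sodium channel genes without Female SNI replicate 3 or Male SNI replicate 2 (0.119 and 0.473) and potassium channel genes without the same libraries (0.067 and 0.568). Erythroid markers lost it without Female SNI replicate 1 or 2 or Male SNI replicate 1 or 3 (0.0963, 0.246, 0.241 and 0.42), and neutrophil markers without Female SNI replicate 1, Female sham replicate 1 or Male SNI replicate 1 or 3 (0.581, 0.0525, 0.701 and 0.42). Complement genes lost it without Female SNI replicate 3 or Male SNI replicate 1 or 3 (0.147, 0.14 and 0.225), and fibroblast and matrix genes without Female SNI replicate 3 or Male SNI replicate 2 or 3 (0.48, 0.402 and 0.352). Interferon-stimulated genes passed only without Male SNI replicate 2, where they were lower in males (adjusted p = 5.24e-08).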

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

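In this part the test of a weaker fall in males was chosen after the result was seen. The tests of male SNI replicate 2 and of the sex labels were written down first.

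A difference between the sexes in the number of genes that fell after injury stood out: 194 genes fell in females and 73 in males, a difference of 121, while 241 and 248 rose. Among 100 relabelings of sex within sham and within SNI, the real one included, 2 gave a difference as large, and the highest other one was 123, which argues against a chance assignment of the labels. The difference depended on which libraries were in the fit. Leaving 1 out also leaves fewer libraries for its sex, which can lower the count there, so these fits do not single out any library. Without female SNI replicate 1, 2 or 3 the counts in females and males were 34 and 46, 37 and 37, and 46 and 38, so the gap was gone, turned or much smaller, and without female sham replicate 1, 2 or 3 they were 99 and 56, 61 and 66, and 54 and 34. Without male SNI replicate 1 they were 157 and 27, and without male sham replicate 1, 2 or 3 they were 113 and 16, 119 and 27, and 137 and 18. Spread added by male SNI replicate 2 stays open: without it the count in males was 154, which the prediction for this cause allows, but the count in females rose to 572 in the same fit, so the gap widened, and without male SNI replicate 3 the counts were 257 and 178. A weaker fall in males stays undecided. The median interaction of the 411 genes that fell on average was 0.0976, positive but under the bound of 0.1. It missed the bound by less than its bootstrap SD of 0.0242, which treats genes as independent and so may be too small. Of 100 relabelings 17 gave a median as large in either direction (largest other 0.133 in size). Sex itself remains an untested explanation, and the spread of the male SNI libraries and a smaller change in males cannot be told apart here.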

How the results depend on the processing

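The fits without both libraries that stood apart, with voom sample quality weights and without the row Rn45s were chosen after seeing the data; all other alternatives here were planned. The one for normalized units did not apply, since the files hold counts. Of 125 results for named genes, 2758 values under the alternatives gave 2570 with the same direction and side of the threshold, 133 no longer past it, 21 newly past it and 34 with the other sign. No called gene changed sign. The cause of these changes was not tested.

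Counts moved by over 1.5 times in these fits. Injury averaged over the sexes, 980: 1848 without both libraries, 2274 with voom weights, 274 with a log2 change of at least 1, and 626 to 1766 without 1 library. Females, 435: 736 with DESeq2, 986 without both, 1724 with voom, 905 with only the 6 libraries, 189 with the fold threshold, and 155 to 1176 without 1 library. Males, 321: 647, 698, 900, 71 and 160 in the same order, and 137 to 601. Sex in sham, 6: 11 with DESeq2, 1 (Tsix) without the sex-linked lists, and 6 to 8. Sex after injury, 6: 13 without both, 1 (Tsix) without the sex-linked lists, and 6 to 7. The interaction stayed at 0 in every fit. The correlation of the sexes, 0.319, was 0.399 under the stricter filter and 0.172 to 0.341 without 1 library. Lists called with an estimated correlation numbered 9 (injury averaged), 8 (females), 8 (males), 2 (sham) and 2 (after injury). Under fry 4 passed in sham and 2 after injury, and 2 passed for the interaction without both libraries. Without 1 library the called lists numbered 17 to 19, 14 to 20, 13 to 18, 0 to 5 (interaction), 4 to 11 and 5 to 10.

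The replicate block gave 936, 437, 295, 0, 6 and 6 genes in the order of the comparisons, and 19, 17, 16, 0, 7 and 9 lists. It ended the calls of Stat3, Il6, C1ra and, in sham, the B cell list, and made one of S100a9. Whether the numbers mark a shared step is not given in the sources used here. Of 18 same-numbered pairs 4 had deviations correlated above 0.1 (-0.212 to 0.739, median 0.018, against 0.00124 for other pairs), among them all 3 pairs of Female sham with Male SNI (0.382, 0.739 and 0.244). Pairs of these 2 groups with different numbers ran from -0.743 to 0.701. Deviations cancel out within a group, so 1 strongly correlated pair partly fixes the others, and the 3 pairs are not separate evidence. Of 12 libraries 6 correlated best with their own number, and a shared step is neither shown nor excluded.

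Log2 changes with the other sign, all of injury averaged over the sexes and of genes not called, were as follows. Without 1 library the range (main value first) was -0.0488, -0.189 to 0.0227 for Gabbr1, -0.0356, -0.128 to 0.0339 for Uchl1, 0.187, -0.00267 to 0.827 for H2-Aa, 0.819, -0.0879 to 1.10 for Lck, 0.490, -0.159 to 0.680 for Rsad2, -0.0783, -0.126 to 0.0127 for Ly6c1, -0.159, -0.361 to 0.0179 for Col1a2, -0.0366, -0.165 to 0.1001 for Scd2, 0.101, -0.0119 to 0.185 for Hadha, -0.641, -2.38 to 0.110 for Ddx3y, -0.0304, -0.141 to 0.131 for Eif2s3y, 0.0531, -1.31 to 0.337 for Xist, -0.175, -0.357 to 0.195 for 5530601H04Rik, and 0.0533, -0.0514 to 0.115 for Utp14a. Without both libraries: Lck -0.261, Rsad2 -0.263, Scd2 0.0332, Eif2s3y 0.134, Xist -1.35 and Utp14a -0.0854. With voom weights: Lck -0.845, Rsad2 -0.137, Scd2 0.0349, Eif2s3y 0.0708, Xist -0.339 and Utp14a -0.0635. Exons of Uchl1, Xist and Utp14a overlap those of Uchl1os, Tsix and 9530027J09Rik, so their values are uncertain.

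At 12476606 to 15520746 counts per library, 8% of simulated 2-fold differences between the responses of the sexes were recovered. Injury labels permuted within each sex gave 980 genes in 1 of 100 splits, the real one, and at most 0 in any other. That share is the smallest that 100 splits can give, and it argues against a chance assignment of the injury labels. Most other splits mixed SNI and sham libraries in a group, which adds to the spread, so their 0 is no measure of false calls. For females (435), males (321), sex in sham (6) and sex after injury (6), 10 splits each are too few for a share under 0.05, and the highest other count was 0 in each. For the interaction 100 of 100 relabelings gave at least the 0 genes found, which any relabeling does, so this is no test; the highest was 7.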

Other observations

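In this part the tests of GC content, of the cell types and of a shared batch were chosen after the result was seen, while the lists and predictions on the body clock and glucocorticoids were written first. How far those last 2 results and the cell type result decide anything was judged only after they were known.

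The genes of 2 lists moved most in single libraries. The median of the interferon-stimulated genes, relative to their mean over the libraries, was 1.79 in Male SNI replicate 2 and between -0.48 and 0.49 in the other 11. In females it was -0.02, 0.49 and 0.45 in SNI replicates 1, 2 and 3 and -0.27 to 0.02 in sham libraries, and the list was also called there. The skeletal muscle markers were at 5.62 in Male SNI replicate 1 and between -1.97 and 1.28 elsewhere.

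Male SNI replicate 2 and Female sham replicate 2, from different sexes and treatments, departed from their groups in the same genes, with a correlation of deviations of 0.739 across 9525 genes; 284 genes were over 4-fold lower and 2 over 4-fold higher in the first, and 46 and 0 in the second. GC content of whole transcripts as the whole cause is argued against by a correlation of 0.736 after its trend was removed, although GC had a Spearman correlation of 0.247 with the deviations of Male SNI replicate 2. It was taken from the longest transcript of each gene, and the GC content of the 3′ ends that the kit reads was not tested. A batch of all libraries numbered 2 is argued against by the other libraries of that number, at 0.021 for Male sham replicate 2 and -0.157 for Female SNI replicate 2. An equal fall of all non-neuronal cells was predicted to lower all marker medians alike, and they moved apart instead. Over 9 cell type lists they ran from -1.36 (neutrophils) to 0.198 (macrophages) in Male SNI replicate 2, a gap of 1.55 with a bootstrap SD of 0.322. The same 2 lists were 0.757 apart in Female sham replicate 2 (SD 0.189). They were picked as the extremes of these values, which the SD does not cover. Relative to their mean over the libraries, neutrophil markers were at 1.28 and 1.05 in Male SNI replicates 1 and 3. They were at -0.21 in Male SNI replicate 2 and between -0.95 and 0.59 in the rest. The gap in Male SNI replicate 2 thus partly reflects the libraries it was compared with, and it cannot decide against an equal fall. Apart from neutrophils and macrophages, all medians but that of endothelial markers (0.005 and -0.15) were below 0 in both libraries. Examples were fibroblast and matrix genes (-0.39 and -0.36) and mural cells (-0.41 and -0.34). Pan-neuronal genes were at 0.26 and 0.23. Lists with a median member under 5 CPM and skeletal muscle, high in Male SNI replicate 1, were not used there. A lower share of many non-neuronal cell types, or of single ones such as neutrophils, stays open. A difference in RNA quality may be another source, and no test of it was made; no biological explanation was tested.

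Between the sexes in sham, Per1 was higher in males (log2 difference 0.71, unadjusted p = 0.000564, rank 13 of all genes), Nr1d1 lower (-0.81, rank 9) and Klf15 higher (1.54, rank 35), none past adjustment (adjusted p = 0.652, 0.405 and 0.938). Per1 and Nr1d1 belong to the body clock, and Per1 and Klf15 are induced by glucocorticoids. A difference in time of dissection could give such values. For the other clock genes high with Per1 limma's fry gave unadjusted p = 0.557, and for those in antiphase unadjusted p = 0.709. Their medians of 0.03 and -0.06 met the bound set in advance against this cause. A median near 0 can hide members that go both ways. Of the 8 genes high with Per1, Nr1d2 was at 0.37 and Ciart at -0.98 (unadjusted p = 0.0319 and 0.0427 in edgeR's test, adjusted p = 0.938 for both). For these 8 genes the mixed test of fry, which counts shifts in either direction, gave unadjusted p = 0.172. A shift both ways was thus not shown, and the cause stays open. A difference in glucocorticoid level may be a candidate explanation: other targets had a median of 0.35 and an unadjusted p = 0.0296 in limma's fry, under the threshold set in advance, but adjusted p = 0.0887 over the 3 lists tested, which leaves it undecided. After injury the same targets had a median of -0.15 (adjusted p = 0.613) and the interaction had adjusted p = 0.18.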
